A study of Homo sapiens with 27 samples.

How the data were processed

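Polyadenylated RNA of untreated PC9 cells was sequenced from TruSeq libraries. Per the labels' protocols, cells were seeded overnight and the RNA had an integrity number of at least 9. The study deposited 1 table of 26364 genes for 27 libraries, 3 for each of 8 clones and the parental whole population. Its count columns hold whole-number counts per gene and library, as the authors deposited them. Its signal columns hold normalized counts made by the authors, each equal to the count divided by 1 factor per library, and these factors ran from 0.886 to 1.178. Per the submitters' processing notes TopHat2 2.0.10, HTSeq 0.6.1p1 and DESeq2 1.6.3 were used with the hg19 build, and the notes state neither the role and settings of each tool nor the gene annotation. The strand setting of the counting was not given. All tests started from the counts.

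The table named genes by symbol, and 6319 genes had no count in any library. Of the symbols 24451 were matched to GENCODE release 29, 23774 by the same symbol and 711 through an older symbol before doubles were removed. That release is built on another genome than hg19, so it served only for names, chromosome, gene order, GC content and length. In 27 pairs of replicate libraries the chi-square per degree of freedom ran from 1.32 to 15.8, and no library was a copy of another. Counting intervals and floors, at 95% and with a floor of 3 counts over a group, cover counting error only. They come from summed counts over library totals, while a ratio printed beside an interval comes from the edgeR fit.

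Clones were grouped by the labelled persister level into high, intermediate and low classes, and counts of the 3 replicate libraries of a clone were summed, since the clone is the unit of replication for a class. edgeR 4.0.16 in R 4.3.3 fitted the 8 sums with TMM normalization, filterByExpr and robust quasi-likelihood, for class contrasts and for the slope on the log2 persister level. The same method on the 27 libraries gave an F test over the 9 populations and a contrast of each clone with the whole population. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. P-values of library-level tests measure the spread between these libraries, which may be technical. The average of 1 minus Pearson r between clone means of different and of the same class was compared by a two-sided exact permutation test over 560 assignments.

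Of 36 gene lists of pathways, lineages and other cell types, 32 had at least 5 tested genes and were tested with camera of limma 3.58.1 on voom values of the clone sums, with a preset correlation of 0.01, then with an estimated correlation and with fry. A gene on a list was also tested with its p-value adjusted over the list alone, which does not correct for the number of lists. Groups, lists, tests, the 12 genes always reported, the rule for named genes and the alternatives were fixed before the data were examined, except for those said to be chosen later.

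For high against low clones the rule took 10 genes per direction with at least 5 CPM in the higher class and every high clone on 1 side of every low clone, by fold change among genes past the threshold and otherwise by unadjusted p. For the trend it took 5 genes per direction by p with 5 CPM in at least 1 clone. For each clone against the whole population it took the 2 genes with the largest and the 2 with the smallest fold change among those past the threshold with 10 CPM in the higher group. Within lists it took the 2 to 4 members with the smallest p in the comparison. Of 63 named genes, 21 overlap another gene of the table in GENCODE 29.

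The tests were checked on simulated counts. For high against low clones edgeR recovered 64.2% of genes changed 2-fold, 95.5% of those changed 4-fold and 97% of those changed 8-fold, with 10 unchanged genes among 181 calls. DESeq2 1.42.0 called 53 unchanged genes of 238, limma-voom with the clone as a random effect 85 of 271, and edgeR with every library as its own replicate 1667 of 1862. For the trend 34.3% of 2-fold and 98.5% of 4-fold genes were recovered. For a clone against the whole population 86.6% of genes changed 1.5-fold and 98.5% of those changed 2-fold were recovered. A moved list was recovered with 0 of the other lists called, a run of 50 lowered genes was found, and a GC slope expected at 0.133 was found at 0.134. Simulated genes varied independently, so the shares recovered and the false calls hold for that setting and need not carry over to these clones. PAQR5, at 3.93-fold between high and low clones, and ALDOC, at 3.46-fold, each had an edgeR adjusted p of 0.734. The list check likewise could not show lists called because their genes vary together. In the data the estimated correlation for high against low clones was 0.835 in the cholesterol synthesis list.

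Alternatives changed the normalization to DESeq2 size factors, the filter (none, or 5 CPM in 3 clones), the tool (DESeq2, limma-voom with the clone as a random effect), the unit of replication, the replicate number as a replicate block, the libraries and clones left out in turn, the place of the whole population, the form of the trend, the distance measure, a log2 fold change of at least 1 and the correlation in camera. A correction of offsets for GC content and length, a fit without libraries that stood apart from their population, and runs of 25 and 100 neighbouring genes were added after the data were seen. Nothing in the deposited table was left out, and the whole population was left out of the class comparisons because it is not a clone.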

Results

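Polyadenylated RNA of untreated PC9 cells, an EGFR-mutant lung adenocarcinoma line, was sequenced in 27 libraries from 9 populations with 3 replicate libraries each. The populations were the parental whole population and 8 clones, each grown from a single cell. The labels give every clone a share of persisters relative to the whole population, which stands at 1, and the series design describes these as shares that persist under gefitinib, an EGFR inhibitor. The high class held 3 clones, B12 at 5.46, Cl.4 at 3.64 and B24 at 3. The intermediate class held 2 clones, Cl.3 at 1.2 and B6 at 1.06, and the low class held 3 clones, A7 at 0.25, A10 at 0.23 and B14 at 0.13. Total counts ran from 9730072 in Cl.3 replicate 1 to 13305520 in A10 replicate 2. The 10 most abundant genes held between 6.32% and 7.89% of the counts of a library.

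Clones of high and low chance to persist were compared to ask which genes differed between them before any drug. ALDOC, an aldolase isoform of glycolysis, averaged 17.5 ± 6.60 CPM (counts scaled to a common library total; SD, n = 3 clones) in the high and 5.05 ± 1.85 in the low clones, a 3.46-fold difference. PAQR5, a membrane progesterone receptor, averaged 16.5 ± 6.74 against 4.20 ± 1.46 CPM, and SSBP2, a single-stranded DNA binding protein, 5.62 ± 0.236 against 2.63 ± 0.415 CPM. SH2B3, an adaptor that restrains JAK2 signalling, averaged 13.9 ± 2.18 against 27.3 ± 1.78 CPM. APLP2, a relative of the amyloid precursor protein, averaged 682 ± 116 against 1267 ± 297 CPM. None of these differences passed the test: edgeR called 0 of 14385 genes, with 968 at an unadjusted p under 0.05 and a smallest adjusted p of 0.734. DESeq2 on the same clone sums called 47 genes, 22 higher and 25 lower in the high clones. limma-voom with the clone as a random effect called 230, 82 higher and 148 lower, and edgeR with every library as its own replicate called 1974. The count of 968 became 2577 without B12, 480 without B24, 602 without Cl.4 and 601 without A10.

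The other genes highest in the high clones by the naming rule were GPR160, at 41.1 ± 2.46 against 26.97 ± 0.523 CPM (log2 difference 0.61, SE 0.10), CUEDC1 (0.53, SE 0.09), CCNG2, an atypical cyclin (0.60, SE 0.12), and DNAL4, a dynein light chain (0.57, SE 0.12). AGBL5, a tubulin deglutamylase (0.50, SE 0.11), YWHAE, the 14-3-3 epsilon protein (0.44, SE 0.10), and FAM132B, which encodes the hormone erythroferrone (1.14, SE 0.26), completed this set. The other genes lowest in them were PLTP, the phospholipid transfer protein, at 87.1 ± 13.4 against 154 ± 8.91 CPM (−0.82, SE 0.14), SIK2 (−0.64, SE 0.12), TBRG1 (−0.78, SE 0.15) and the mitochondrial thiolase ACAT1 (−0.60, SE 0.13). DDX10, an RNA helicase (−0.54, SE 0.12), PPP2R1B, a scaffold subunit of protein phosphatase 2A (−0.66, SE 0.15), AASDHPPT (−0.52, SE 0.12) and the noncoding RNA SNHG7 (−0.50, SE 0.11) completed these. All 20 named genes were called by DESeq2 and 17 by limma-voom, and each had an adjusted p of 0.734 by edgeR. The genes were picked from the same counts by separation and unadjusted p, so these calls are not independent evidence. Other splits of the high and low clones gave 1 to 225 calls by DESeq2 and 0 to 527 by limma-voom. The largest counts came from splits that keep Cl.4 and B24 in 1 group. Splits that part these clones gave at most 6 and 11. Of the 10 lower genes, 7 lie on chromosome 11 in GENCODE release 29 (SIK2, TBRG1, ACAT1, DDX10, APLP2, PPP2R1B and AASDHPPT), as did 27.3% of the genes lower at an unadjusted p under 0.05 against 5.7% of the genes tested. Among these genes SIK2 and PPP2R1B overlap each other on opposite strands, and AGBL5, DNAL4, PLTP, SH2B3, SNHG7, TBRG1 and AASDHPPT each overlap another counted gene, so their values are uncertain where reads of the neighbour were counted.

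Neighbouring genes on chromosome 11 were lower together in the high clones. Of 50 neighbouring genes from TRAPPC4 to ST3GAL4-AS1, in the gene order of GENCODE 29, 48 had a lower mean in the high than in the low clones, with a median log2 difference of −0.66 and quartiles of −0.77 and −0.55. Against the whole population the median of these genes was −0.98 in B24, where 47 were called lower by edgeR, −0.35 in Cl.4, −0.31 in B12 and −0.21 in Cl.3. It was 0.33 in A10, where 33 were called higher, and between 0.06 and 0.11 in A7, B14 and B6. In runs of 100 genes the lowest reached from DDX10 to ARHGAP32 on the same chromosome, with 96 of 100 genes lower and a median of −0.62. Of the 7 lower genes named on chromosome 11 it holds 4 (DDX10, SIK2, PPP2R1B and TBRG1), and the shorter run holds TBRG1. In runs of 25 genes the lowest was from GRAMD1B to ST3GAL4-AS1, with a median of −0.72. The highest run depended on its length. On chromosome 6, 50 of 50 neighbouring genes from SASH1 to C6orf120 had a higher mean in the high than in the low clones, with a median of 0.51. Against the whole population their median was 0.51 in Cl.4, 0.57 in B24 and 0.48 in the intermediate clone Cl.3, but −0.15 in the high clone B12. With 25 genes the highest run was on chromosome 6 as well, from PCMT1 to EZR (median 0.52), but with 100 it was on chromosome 3, from RABL3 to HPS3, with 98 of 100 genes higher and a median of 0.46. Of runs picked on every other gene the highest was also on chromosome 3, where 48 of the 50 genes in between were higher. All these runs were the extremes of a search over the chromosomes that was not fixed beforehand. Runs were not particular to the class difference. Against the whole population neighbouring genes had a Pearson r from 0.15 in B12 to 0.33 in A10. The lowest run of 50 genes had a median of −1.49 in Cl.4 on chromosome 4, and on chromosome 22 of −0.87 in Cl.3 and −0.805 in A10.

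**Figure D1:**
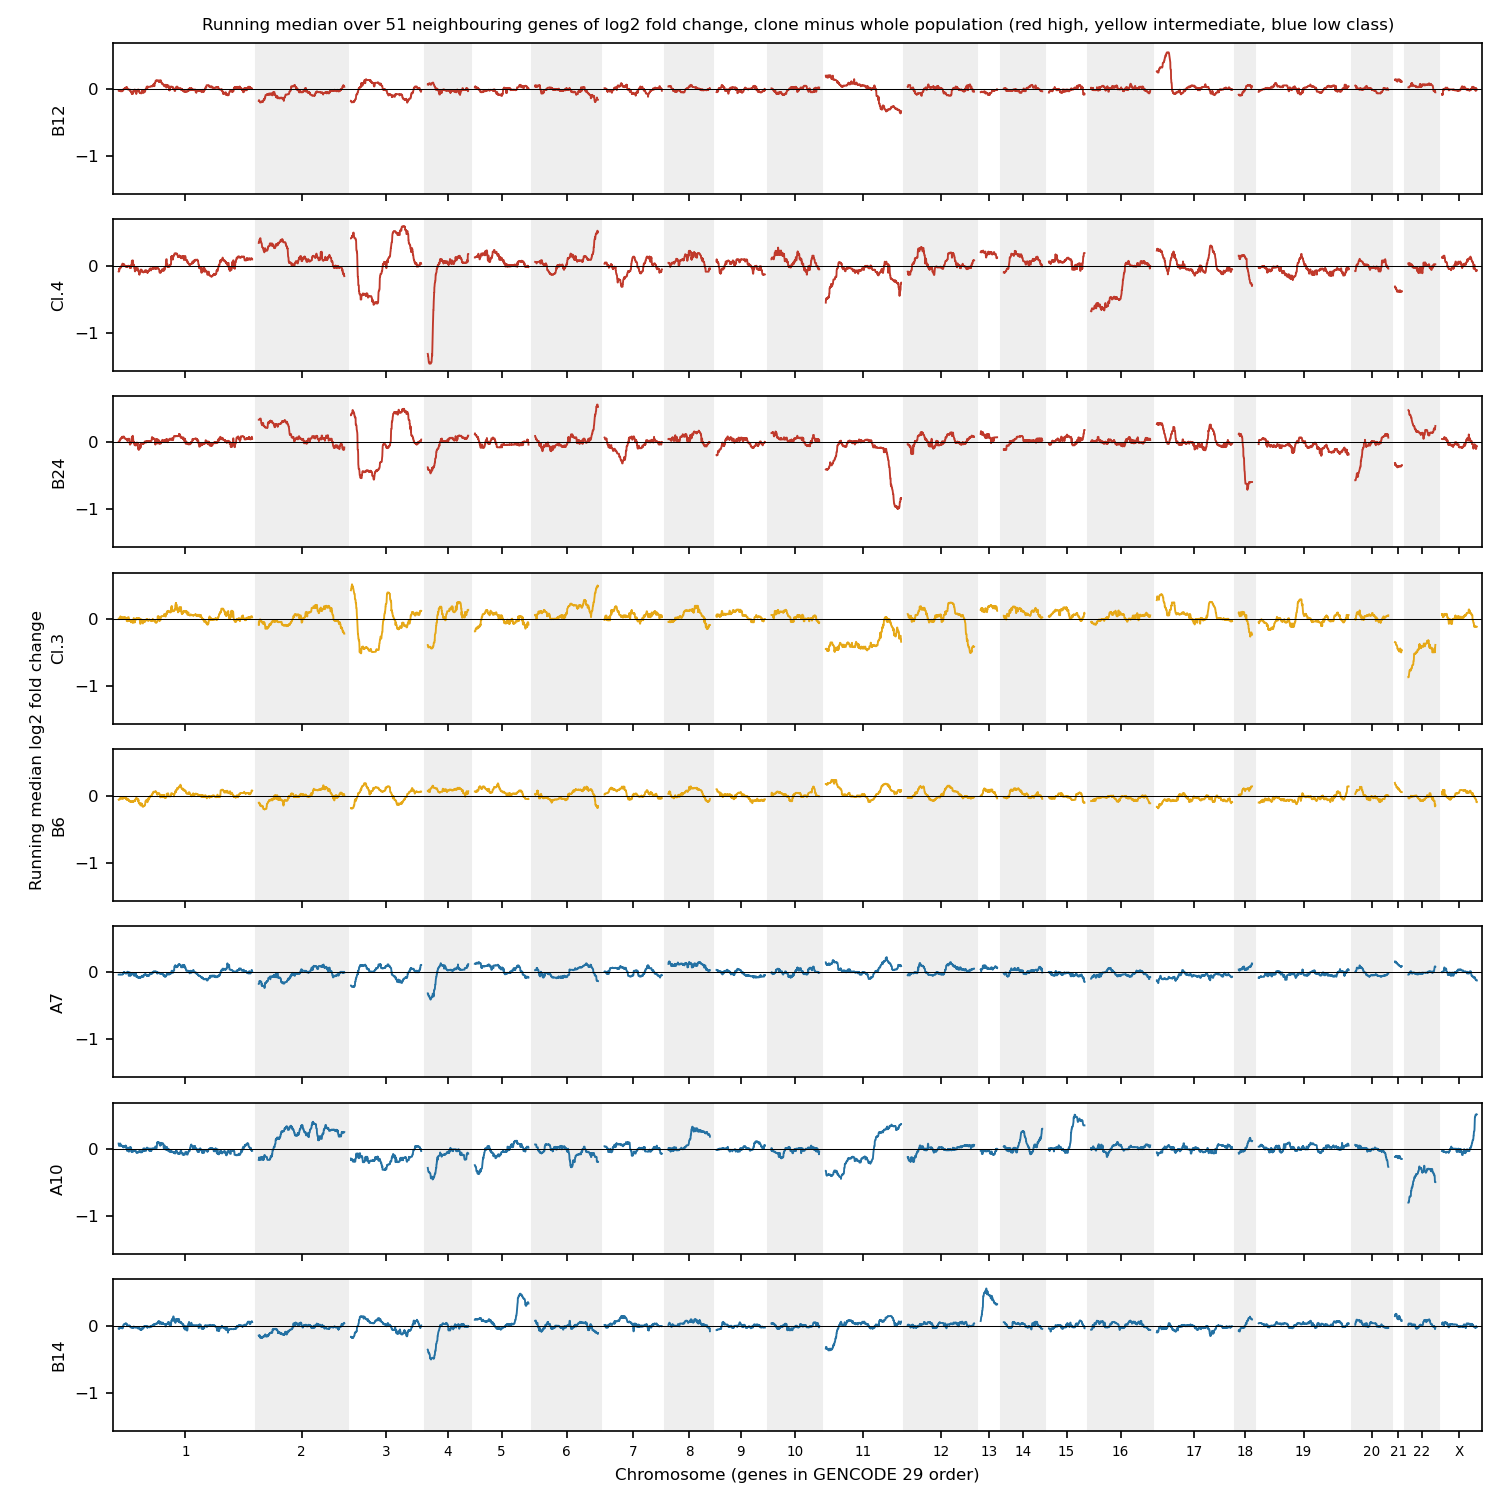
Running median of the log2 fold change against the whole population along the chromosomes, in GENCODE 29 gene order, with a panel for each of the 8 clones. Neighbouring genes on chromosome 11 lie low in B24, where the median from TRAPPC4 to ST3GAL4-AS1 was −0.98, and neighbouring genes on chromosome 4 in Cl.4, where that from MAEA to CPZ was −1.49.

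SIK2 is a member of the list of kinases known to phosphorylate IRS proteins on serine, lies in the chromosome 11 run of 100 genes, and was below every low clone in each high clone, at 44.2 ± 2.17 against 68.9 ± 6.80 CPM. Over all genes 0 of the 23 tested members of that list were called, and 1 was called adjusted over the list alone (SIK2, edgeR adjusted p = 0.0125). In the same way 0 members passed over all genes and 1 adjusted over the list alone in the glycolysis and hypoxia response (ALDOC, adjusted p = 0.0371) and in the alveolar and lung lineage list (the surfactant protein gene SFTPB, log2 difference −0.99, SE 0.23, adjusted p = 0.0378). None of the other lists tested had a member called in this comparison, over all genes or adjusted over the list alone.

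Of the 24 tested genes of cholesterol synthesis, 22 had a positive log2 difference of high minus low clones, with a median of 0.33 (limma camera, adjusted p = 0.0045, and 0.960 with an estimated correlation between genes). ACAT2, an acetyl-CoA thiolase, averaged 84.5 against 50.9 CPM (log2 difference 0.73, SE 0.26) and SREBF2, the transcription factor that drives the pathway, 349 against 250.1 CPM (0.49, SE 0.32). Of the 19 tested genes of HLA class I and antigen processing, 16 had a negative difference, with a median of −0.22 (limma camera, adjusted p = 0.0104, and 0.960 with an estimated correlation). The peptide transporter gene TAP2 differed by −0.42 (SE 0.14) and HLA-C by −0.32 (SE 0.13). Against the whole population the high clone B12 had 3 of 18 tested HLA class I members called higher and 0 lower, with a median of −0.002. By fry 0 lists were called. Without A10 the adjusted p was 0.572 for cholesterol synthesis and 0.310 for HLA class I. For cholesterol synthesis it was 0.115 without B12 and 0.0829 without Cl.4. The other lists tested had a camera adjusted p from 0.136 to 0.989.

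IRS1, the insulin receptor substrate in the series title, averaged 79.1 ± 15.7 CPM in the high, 100.1 ± 10.6 in the intermediate and 101 ± 8.35 in the low clones. The log2 difference of high and low clones was −0.35 (SE 0.16, 95% interval −0.73 to 0.03, edgeR adjusted p = 0.741). Against the whole population, at 93.2 ± 6.73 CPM (SD, n = 3 libraries), IRS1 was lower in B12, at 61.0 ± 2.18 CPM (log2 fold change −0.62, SE 0.08, adjusted p = 4.21e-07), and no other clone was called. INSR, the insulin receptor, was lower in A7 (−1.52, SE 0.23), A10 (−0.78, SE 0.20) and B6 (−1.79, SE 0.24), and in B14 with edgeR (−0.61, SE 0.20, adjusted p = 0.0329) though not with DESeq2 (adjusted p = 0.0683) or without replicate 2 or 3 of every population (adjusted p of 0.148 and 0.244). IRS2 was higher in Cl.4 (0.27, SE 0.09), B24 (0.32, SE 0.08) and Cl.3 (0.33, SE 0.09), calls that ended without replicate 1 of every population (adjusted p of 0.106, 0.0601 and 0.0612). Over the 28 tested genes of the insulin and IGF receptor axis the median difference of high and low clones was 0.06 (camera adjusted p = 0.480).

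Between high and low clones EGFR averaged 332 ± 33.6 against 471 ± 98.2 CPM (log2 difference −0.50, SE 0.31, edgeR adjusted p = 0.7865). INSR differed by 0.94 (SE 0.44), DUSP6 by −0.46 (SE 0.18), VIM by −0.55 (SE 0.71) and IGF1R by 0.42 (SE 0.29). The other differences were MET −0.23 (SE 0.31), AXL 0.21 (SE 0.53), ERBB2 0.21 (SE 0.13), ERBB3 −0.18 (SE 0.16), IRS2 0.05 (SE 0.16) and CDH1 0.01 (SE 0.11). edgeR called none of these genes between the classes. EGFR was higher than in the whole population, at 375 ± 8.58 CPM, in A7, at 574 ± 28.1 (log2 fold change 0.61, SE 0.08), and in B6 (0.48, SE 0.08), and lower in Cl.3, at 218 ± 8.85 CPM (−0.81, SE 0.09). MET was lower in B12 (−0.85, SE 0.08) and B14 (−0.39, SE 0.08) and higher in Cl.4 (0.38, SE 0.08) and A7 (0.44, SE 0.08). AXL, a receptor linked to resistance against EGFR inhibitors, was higher in Cl.4, at 220 ± 3.61 CPM against 108 ± 6.19 (1.03, SE 0.07), and in A7 (0.77, SE 0.07), and lower in Cl.3, at 29.1 ± 2.88 CPM (−1.92, SE 0.08). DUSP6, a phosphatase induced by ERK signalling, was lower in B12 (−0.52, SE 0.06) and Cl.4 (−0.62, SE 0.06) and higher in A10 (0.28, SE 0.06) and B6 (0.48, SE 0.06). VIM, the mesenchymal filament vimentin, was higher in A7 (2.12, SE 0.12), B24 (1.496, SE 0.131), A10 (1.11, SE 0.13) and Cl.4 (1.06, SE 0.14) and lower in Cl.3 (−1.61, SE 0.19) and B12 (−0.91, SE 0.17). ERBB3 was lower in Cl.4 (−0.63, SE 0.07) and B6 (−0.40, SE 0.07), ERBB2 in B6 (−0.58, SE 0.09), and CDH1, E-cadherin, in B6 (−0.49, SE 0.07) and Cl.4 (−0.27, SE 0.07). IGF1R was higher in Cl.4 (0.48, SE 0.10). Of the 53 calls made for the 12 genes fixed beforehand in the 8 clones, 30 held under every alternative and 23 ended under at least 1. The calls named so far for EGFR, MET, AXL, DUSP6, VIM, ERBB2, ERBB3, CDH1 and IGF1R are among those that held. The calls of these genes that ended were IGF1R, higher in B24 (0.42, SE 0.11), Cl.3 (0.35, SE 0.11) and A10 (0.28, SE 0.10) and lower in A7 (−0.41, SE 0.11), B14 (−0.46, SE 0.11) and B6 (−0.46, SE 0.11), and EGFR, higher in B14 (0.28, SE 0.08) and lower in Cl.4 (−0.28, SE 0.08) and B24 (−0.26, SE 0.08). They were also AXL, higher in B24 (0.25, SE 0.07) and B6 (0.28, SE 0.07), DUSP6, lower in B24 (−0.20, SE 0.06) and B14 (−0.21, SE 0.06), and VIM, higher in B14 (0.52, SE 0.14). The last were ERBB2, lower in Cl.3 (−0.30, SE 0.09) and A10 (−0.40, SE 0.09), ERBB3, lower in Cl.3 (−0.27, SE 0.07), and CDH1, lower in Cl.3 (−0.19, SE 0.07) and A7 (−0.33, SE 0.07). Fits without a replicate number hold fewer libraries per population, so a call can end there with little change in size. CDH1 in A7, for example, was at −0.335 without replicate 1, where its call ended. EGFR and VIM overlap antisense genes and ERBB2 overlaps MIEN1 and PGAP3, so their values are uncertain where reads of these were counted.

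**Figure D2:**
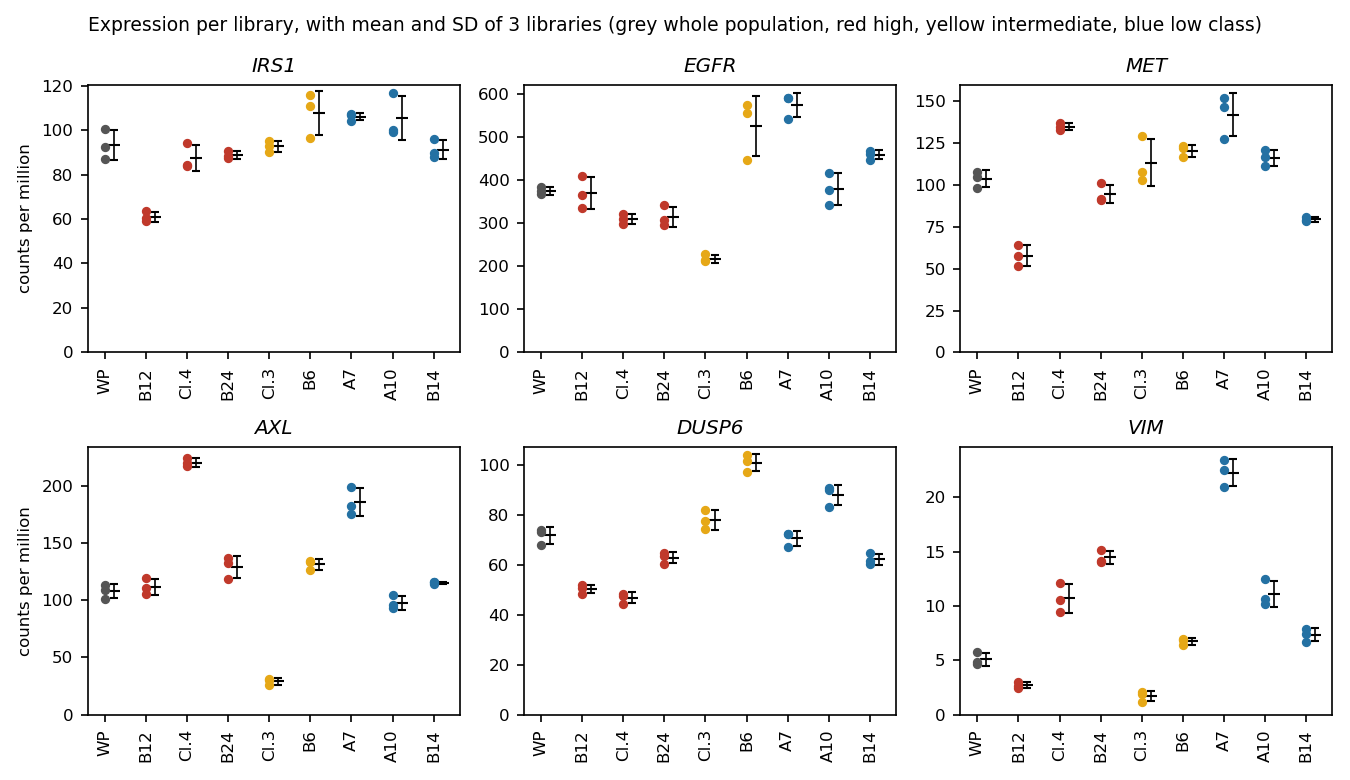
Expression in CPM of 6 genes in each library (points, 3 per population) with the mean and SD beside them, for the whole population (WP) and the 8 clones ordered by class. AXL and VIM were lowest in Cl.3, MET and IRS1 in B12, and VIM was highest in A7 at 22.3 CPM.

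Between high and intermediate clones, ALDOC averaged 17.5 against 6.52 CPM and FAM132B 14.5 against 4.06 CPM, with log2 differences of 1.44 and 1.86. Between intermediate and low clones SH2B3 averaged 17.5 against 27.3 CPM and PLTP 90.05 against 154 CPM. edgeR called 0 genes in either comparison, with 613 and 352 at an unadjusted p under 0.05 and smallest adjusted p of 1 and 0.999. DESeq2 called 26 genes higher and 3 lower between high and intermediate clones, and limma-voom with the clone as a random effect 34 and 5. Between intermediate and low clones DESeq2 called 5 genes and limma-voom 0. Those 5, chosen after their values were seen, were TMEM132A (−0.90), ACTL8 (−2.78), SYT7 (−1.65), PLTP (−0.79) and RNF212 (10.14), each with its log2 difference. RNF212 averaged 0.01 CPM in the low clones, near the floor, so the size of its difference is uncertain. The count of 613 became 1598 without B12, 375 without B24 and 1151 without B6, and that of 352 became 1393 without B6, 172 without Cl.3, 233 without A10 and 219 without B14.

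Among genes with a positive slope of expression on the log2 persister level of the 8 clones, the smallest unadjusted p belonged to GPR160 (0.13 per doubling, SE 0.03), SSBP2 (0.24, SE 0.05), CUEDC1 (0.12, SE 0.02), YWHAE (0.10, SE 0.02) and GLOD4 (0.11, SE 0.02). Among genes with a negative slope it belonged to SH2B3 (−0.21, SE 0.04), the transporter genes SLC35F2 (−0.12, SE 0.02) and SLC37A2 (−0.15, SE 0.03), SIK2 (−0.14, SE 0.03) and ACAT1 (−0.13, SE 0.03). None passed: edgeR called 0 of 14091 genes, with 708 at an unadjusted p under 0.05 and a smallest adjusted p of 0.904. The count of 708 became 2300 without B12, 458 without Cl.4 and 441 without B24. DESeq2 called 12 rising and 13 falling genes and limma-voom with the clone as a random effect 12 and 44. GLOD4 overlaps MRM3 on the opposite strand, so its value is uncertain. Camera called 3 lists: cytosolic ribosomal proteins, with 33 of 37 slopes negative and a median of −0.02 per doubling (adjusted p = 0.0071), HLA class I and antigen processing, with 15 of 19 negative (adjusted p = 0.0071), and cholesterol synthesis, with 22 of 24 positive (adjusted p = 0.0205). With an estimated correlation each adjusted p was 0.927, and over all genes 0 members were called in any list. Adjusted over the list alone, 1 member was called in the alveolar and lung lineage list (SFTPB, edgeR adjusted p = 0.0145) and 1 in the list of kinases that phosphorylate IRS proteins on serine (SIK2, edgeR adjusted p = 0.0225). This adjustment does not correct for the number of lists. The call of the ribosomal list ended without B14 (adjusted p = 0.840) and without B12 (adjusted p = 0.242). That of HLA class I ended without A10 or B14 (adjusted p of 0.328 and 0.101), and that of cholesterol synthesis without B12, Cl.4 or A10 (adjusted p of 0.463, 0.629 and 0.588).

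Across the 9 populations 10974 of 13252 tested genes (82.8%) differed by edgeR's quasi-likelihood F test, and the median share of a gene's variance that lay between populations was 74.5%. The first principal component (30.9% of variance) set Cl.4, B24 and Cl.3, with scores of 32.2 to 41.3, apart from the other 5 clones and the whole population, with scores of −35.8 to −8.76. Clone means of different classes were separated by an average distance (1 minus Pearson r of log2 CPM) of 0.0288 and those of the same class by 0.0273. The difference of 0.00153 had a two-sided exact permutation p of 0.729 over 560 assignments of the 8 clones. The 3 classes held a median of 25.4% of the variance of a gene's clone means, against 24.2% as the median over the 560 assignments, of which 41.8% gave at least the real value. All 3 high clones lay above all 3 low clones in 878 genes and below them in 848, together 12% of the tested genes, where chance gives 10%.

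**Figure D3:**
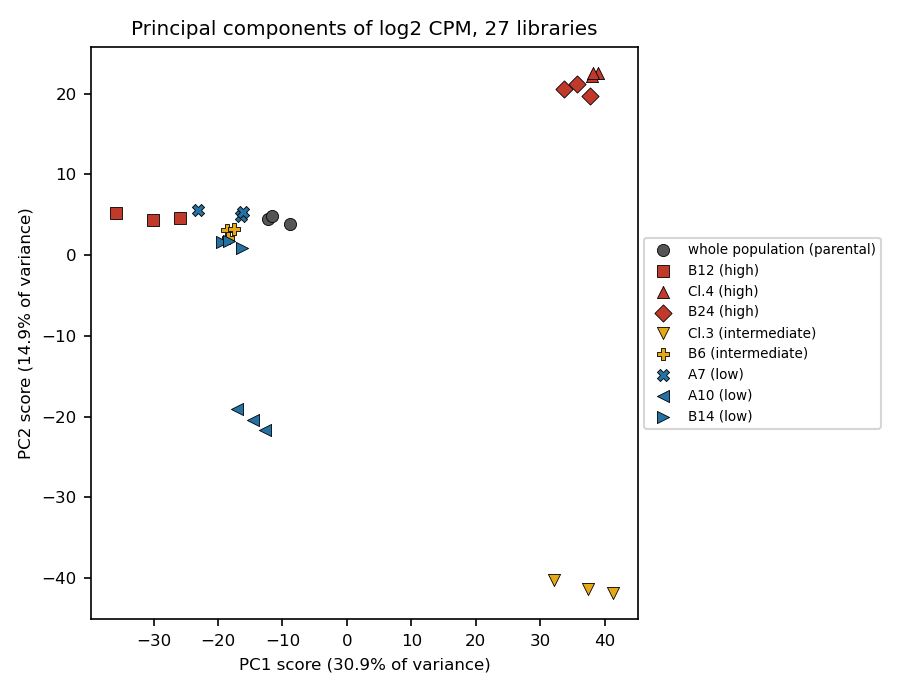
Scores of the 27 libraries on the first and second principal components of log2 CPM (30.9% and 14.9% of variance), with a marker per population and a colour per class. The high clone B12 has negative first scores, as do the 3 low clones, while those of Cl.4 and B24 are at 33.6 or above.

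Each clone was compared with the whole population to describe how far its expression differed from that of the parental culture. Rose and fell stand for higher and lower than in the whole population, since no change over time was measured. In B12, MFGE8, a secreted bridge between apoptotic cells and phagocytes, rose 9.27-fold (log2 SE 0.14) and L1CAM, a neural adhesion molecule, rose 7.42-fold (SE 0.09). MAGEC1, a cancer-testis antigen, was lower 150-fold (SE 0.19), and VCX3B 28.1-fold (SE 0.15), a value that is uncertain because VCX3B belongs to a multicopy family. In Cl.4, CDH13, a cadherin, rose 11.5-fold (SE 0.18) and KCNJ12, a potassium channel, 5.45-fold (SE 0.16). HBE1, embryonic globin, had 0 counts in Cl.4 and was at least 125-fold lower, and OR51B5 at least 221-fold lower, against a floor of 3 counts over the group. In B24, TNC, the matrix protein tenascin-C, rose 15.6-fold (SE 0.22) and the kinase gene JAK2 7.97-fold (SE 0.19). MCAM, an adhesion molecule, was lower 78.1-fold (SE 0.18) in B24, and MUC6, a mucin, had 2 counts there, a ratio of 227 with a counting interval of 73.3 to 2200. In Cl.3, MARCH1, a ubiquitin ligase, rose 8.84-fold (SE 0.23), and the pseudogene OSTCP1 25.9-fold (SE 0.21), which is uncertain because of its parent gene. TRPM2, a cation channel, had 2 counts in Cl.3 (ratio 223, interval 68.4 to 2060) and FSTL5 had 1 (ratio 510, interval 117 to 26000).

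In A7, MFAP5, a microfibril protein, rose 32.6-fold (SE 0.23), and PTN, the growth factor pleiotrophin, had 3 counts in the whole population against 363 in A7 (ratio 109, interval 41.2 to 591). MUC4, a membrane mucin, was lower 11.6-fold (SE 0.28) in A7 and BARX2, a homeobox gene, 18.6-fold (SE 0.20). In A10, MLLT11 rose 7.59-fold (SE 0.11) and SPHK1, sphingosine kinase, 6.94-fold (SE 0.20), while COL12A1 was lower 13.4-fold (SE 0.21) and KRT13, a keratin of stratified epithelium, 15.6-fold (SE 0.11). In B14, AOC1, a diamine oxidase, rose 18.1-fold (SE 0.13) and LOC101448202 6.35-fold (SE 0.12), while OR51B5 was lower 82.2-fold (SE 0.20) and HBE1 had 2 counts (ratio 164, interval 54.9 to 1650). In B6, LOC101448202 rose 4.78-fold (SE 0.13) and CSNK1E, a casein kinase, 2.59-fold (SE 0.29), a call that ended without replicate 2 (adjusted p = 0.0781). MUC4 was lower 14.8-fold (SE 0.30) in B6 and TMPRSS4, a serine protease, 4.06-fold (SE 0.12). HBE1 and OR51B5 overlap each other, as MCAM does CBL, L1CAM does LCA10, MLLT11 does CDC42SE1, SPHK1 does PRPSAP1 and CSNK1E does a readthrough gene, so these values are uncertain where reads of the neighbour were counted. Every named gene passed the edgeR test against the whole population, with adjusted p from 6.51e-23 for KRT13 in A10 to 0.0016 for CSNK1E in B6.

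Over all 13252 tested genes 2167 rose and 3158 fell in Cl.3, and 2520 and 2823 in Cl.4. In B24 2161 rose and 2567 fell, and in A10 1830 and 2217. No list was tested against the other genes within a clone, so member counts are to be read beside these. Of 24 tested genes of cholesterol synthesis 23 fell and 0 rose in A10, 23 fell and 0 rose in Cl.3, and 16 rose and 1 fell in Cl.4, with the same counts adjusted over the list alone. The other 2 high clones did not follow Cl.4: 11 fell and 1 rose in B24 (12 and 1 adjusted over the list alone), and 1 fell and 0 rose in B12 (the same adjusted over the list alone). INSIG1, a sterol sensor, changed by −1.43 (log2, SE 0.06) in A10, −1.23 (SE 0.06) in Cl.3 and 0.67 (SE 0.06) in Cl.4, and HMGCS1, HMG-CoA synthase, by −1.74 (SE 0.10) in A10. SCD, the desaturase of fatty acid synthesis, fell by 1.61 in Cl.3 and by 1.28 in A10 on the log2 scale, and of 19 tested members of its list 11 fell and 0 rose in each of these clones (13 and 12 fell and 0 and 1 rose adjusted over the list alone). Of 30 G2/M mitotic genes 29 rose in Cl.3 and 22 rose and 1 fell in Cl.4, also adjusted over the list alone. AURKA, a mitotic kinase, rose by 0.45 (SE 0.05) in Cl.3, cyclin A2 (CCNA2) by 0.42 (SE 0.05), and KIF20A, a mitotic kinesin, by 0.52 (SE 0.06) in Cl.3 and 0.50 (SE 0.06) in Cl.4. In Cl.3, replicates 2 and 3 stood apart from each other along the main axis of replicate spread, which follows GC content. Without them and the other libraries that stood apart from their population the median log2 fold change of the G2/M list in Cl.3 was 0.44, against 0.40 with all libraries. This leaves Cl.3 with 1 library, whose spread is taken from the other populations. Replicates 2 and 3 lay at opposite ends of the axis, so leaving both out could hardly move the Cl.3 mean along it.

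**Figure D4:**
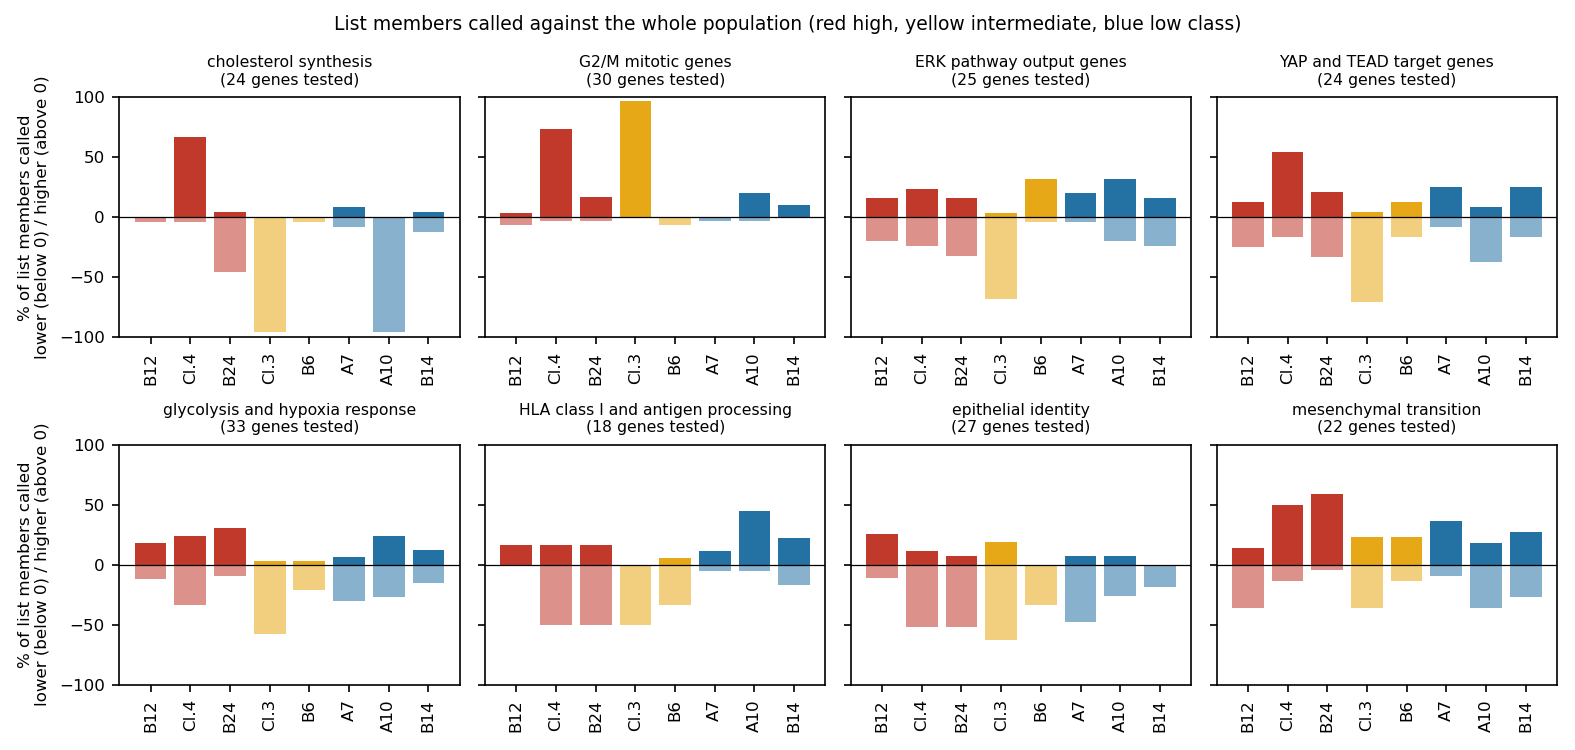
Share of the members of 8 fixed gene lists called higher (above 0) or lower (below 0, paler) than in the whole population in each clone, in percent of the members tested. Cholesterol synthesis was lower in 23 of 24 members in Cl.3 and A10, and G2/M mitotic genes were higher in 29 of 30 members in Cl.3.

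Cl.3 differed from the whole population across several lists, and over all 13252 tested genes 2167 rose and 3158 fell there. The lists were not tested against other genes within a clone. Of the 25 ERK pathway output genes 17 fell and 1 rose in Cl.3 (the same adjusted over the list alone), with EPHA4 at −1.36 (SE 0.12) and FOSL1, an AP-1 subunit, at −0.94 (SE 0.09). Of the 24 YAP and TEAD target genes 17 fell and 1 rose (18 and 1 adjusted over the list alone), with IGFBP3 at −1.83 (SE 0.05) and CYR61 at −1.13 (SE 0.10). In Cl.4 the same YAP list had 13 members higher and 4 lower (15 and 4 adjusted over the list alone), with IGFBP3 lower at −1.12 (SE 0.05) and DLC1 higher at 1.05 (SE 0.14). Of the 33 genes of glycolysis and hypoxia response 19 fell and 1 rose in Cl.3 (20 and 2 adjusted over the list alone), with LDHA, lactate dehydrogenase, at −1.50 (SE 0.06) and SLC2A3, a glucose transporter, at −3.18 (SE 0.12). Of the 22 mesenchymal transition genes 13 rose and 1 fell in B24 (14 and 2 adjusted over the list alone), 11 rose and 3 fell in Cl.4 (11 and 4) and 8 rose and 2 fell in A7 (8 and 3), while in B12 3 rose and 8 fell (5 and 12). More also fell than rose in A10, where 4 rose and 8 fell (4 and 10), and in Cl.3, where 5 rose and 8 fell (5 and 9). SERPINE2 rose by 1.21 (SE 0.05) in B24 and by 0.83 (SE 0.05) in Cl.4, and the integrin ITGA5 by 1.43 (SE 0.07) in B24. Of the 27 epithelial identity genes 17 fell and 5 rose in Cl.3 (the same adjusted over the list alone), 14 fell and 3 rose in Cl.4 (15 and 3), 14 fell and 2 rose in B24 (20 and 3) and 13 fell and 2 rose in A7 (17 and 2), while in the high clone B12 7 rose and 3 fell (8 and 3). PRSS8, the protease prostasin, was at −5.24 (SE 0.17) in Cl.3, and ST14, matriptase, at −1.43 (SE 0.08) in B24. Of the 18 HLA class I and antigen processing genes 9 fell and 3 rose in Cl.4 (11 and 4 adjusted over the list alone), 9 fell and 3 rose in B24 and 9 fell and 0 rose in Cl.3 (the same adjusted over the list alone). In A10, 8 of them rose and 1 fell (8 and 2 adjusted over the list alone). The high clone B12 did not follow Cl.4 and B24, with 3 higher, 0 lower and a median of −0.002. A fit without Cl.3 replicates 2 and 3 and the other libraries that stood apart again leaves Cl.3 with 1 library, so only medians are given. In Cl.3 the median log2 fold change went from −0.312 to −0.358 for ERK output genes and from −0.536 to −0.545 for YAP targets. For epithelial genes it went from −0.253 to −0.235. Cl.3 replicates 2 and 3 lay at opposite ends of the main axis of replicate spread. Leaving both out could hardly move the Cl.3 mean along it, so these medians do not test an effect of those libraries.

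By edgeR 1007 genes were higher and 1053 lower than in the whole population in B12, 2520 and 2823 in Cl.4, 2161 and 2567 in B24, and 2167 and 3158 in Cl.3. The counts were 886 and 1059 in A7, 1830 and 2217 in A10, 1006 and 1294 in B14, and 686 and 1045 in B6. Leaving out replicate 1 of every population moved the higher count by over 1.5 times in each of the 8 clones, to 460 in B12, 1537 in Cl.4, 1327 in B24, 1295 in Cl.3, 364 in A7, 1023 in A10, 346 in B14 and 233 in B6. Leaving out replicate 3 did so in each but A10 (1238), to 486 in B12, 1675 in Cl.4, 1428 in B24, 1227 in Cl.3, 459 in A7, 477 in B14 and 240 in B6. The lower count moved as far in both cases in B12 (496 and 566), A7 (506 and 524), A10 (1282 and 1389), B14 (592 and 707) and B6 (531 and 429). Fits without a replicate number hold fewer libraries per population, which by itself can lower the number of calls. In each of the 8 clones most called genes were lower, and with a correction for GC content and length most were higher. The share of called genes that were higher went from 48.9% to 57% in B12, from 47.2% to 54.5% in Cl.4, from 45.7% to 56.8% in B24 and from 40.7% to 57.3% in Cl.3. It went from 45.6% to 52.4% in A7, from 45.2% to 52.1% in A10, from 43.7% to 56.5% in B14 and from 39.6% to 52.2% in B6. In Cl.4 the corrected counts were 3469 higher and 2896 lower. With it the median of the HLA class I list went from −0.24 to −0.07 in Cl.4, from −0.21 to −0.10 in B24 and from −0.25 to −0.09 in Cl.3, and that of the glycolysis list from −0.25 to −0.10 in Cl.3. That of the epithelial list went from −0.25 to −0.11 in Cl.3, from −0.27 to −0.14 in Cl.4 and from −0.27 to −0.16 in B24.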

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

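The comparisons between pairs of clones in this part were chosen after the calls against the whole population were seen, as were the GC and length correction, the fit without libraries that stood apart and the tests of the spread between replicate libraries. The search for runs of neighbouring genes was not fixed beforehand. The genes and lists of the next paragraph stand here because clones differed from the whole population in opposite directions. Each pair is the highest and the lowest of the 8 clones for that gene, or for a list those with most members called higher and most called lower. They were picked after the calls were seen, so a p-value of the pair would overstate the evidence and none is given. Counts of list members called between the clones of a pair rest on such p-values. They overstate the evidence in the same way and only describe the pair.

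AXL was 2.95 higher on the log2 scale in Cl.4 than in Cl.3 (SE 0.08), and VIM 3.72 higher in A7 than in Cl.3 (SE 0.15). EGFR was 1.42 higher in A7 than in Cl.3 (SE 0.09) and MET 1.29 higher in A7 than in B12 (SE 0.08). DUSP6 was 1.10 higher in B6 than in Cl.4 (SE 0.06), and IGF1R 0.94 higher in Cl.4 than in B14 (SE 0.11). Of 24 genes of cholesterol synthesis 23 were called higher by edgeR in Cl.4 than in Cl.3, with a median log2 difference of 1.53. Of 24 YAP and TEAD targets 21 were called higher in Cl.4 than in Cl.3 (median 0.79). Of 17 receptor tyrosine kinases other than EGFR and their ligands 11 were called higher in B24 than in Cl.3 (median 0.74). The pairs were picked by calls of the same list members, so these list counts are not a test of the difference. EGFR and VIM overlap antisense genes, so their values are uncertain where those were counted.

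Genes on chromosome 11 from TRAPPC4 to ST3GAL4-AS1 were lower in the high than in the low clones by a median of −0.66. A bias by GC content or gene length is argued against, since the median was −0.68 with the correction. A regional difference shared by neighbours, such as a change in copy number, is a candidate explanation: of runs picked on every other gene, 100% of the 50 genes in between went the same way (median −0.62). Copy number itself was not measured, and the biological class difference stays open. The 10 splits of the 6 clones are too few for a share under 0.05. In differences of mean log2 values of these clones, without a fit, the real split gave a run of 0.74. The highest of the other splits gave 0.55.

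G2/M mitotic genes were higher than in the whole population in Cl.3 (29 of 30) and Cl.4 (22 of 30). GC content or gene length as the whole cause is argued against, since the median went from 0.40 to 0.44 (0.438) in Cl.3 and from 0.31 to 0.32 (0.324) in Cl.4 with the correction. Without the libraries that stood apart the median in Cl.3 was 0.44, which cannot decide whether they are a cause. Cl.3 replicates 2 and 3 lay at opposite ends of the main axis of replicate spread (scores of 20.2 and −17.7), with replicate 1 between them (−2.51). Leaving both out could therefore hardly move the Cl.3 mean along that axis. This also leaves Cl.3 with 1 library, which is assumed to vary like the others. A difference in the share of dividing cells between cultures or clones may underlie the higher G2/M genes and was not tested.

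The main axis of the spread between replicate libraries held 21.1% of the variance within populations, with B12 replicates 1 and 2, Cl.3 replicates 2 and 3 and A7 replicate 2 at its ends. Its gene loadings correlated with GC content at 0.79 across 12919 genes, which are not independent replicates, so a GC bias of library preparation or sequencing is a candidate explanation. A batch shared by libraries with the same replicate number is another: the scores differed by number (exact permutation p = 0.0088 within populations), with replicate 2 positive in 8 of 9 populations and 43.6% of the axis between numbers. Over all genes 26 of 108 pairs of same-numbered libraries correlated above 0.1 and 34 at or below 0, so the numbers do not bring every pair together. Neither candidate excludes the other, since a batch can act through GC content, and a biological explanation was not tested.

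For high against low clones the 10 splits of 6 clones are too few for a share under 0.05. The real split gave 968 genes at an unadjusted p under 0.05 against 1695 as the highest other, with 4 splits at least as large. Counts of splits as large include the real one throughout. With every library as its own replicate it gave 1974 calls against 3593 (4 as large), by DESeq2 47 against 225 (3 as large), by limma-voom 230 against 527 (3 as large), and by camera 2 lists against 8 (9 as large). The 4 splits that keep Cl.4 and B24 in 1 group gave 968, 1012, 1525 and 1695 genes and the other splits 176 to 344, which points to a structure of the samples. For the trend chance could not be excluded: 30 of 100 orders of the levels gave at least the 708 genes of the real order (highest other 3417) and 90 gave at least its 3 lists (highest other 11). For the F test chance was excluded, with 10974 genes against 1 as the highest other and 1 of 40 splits as large. Each clone against the whole population has 10 splits of 6 libraries, too few for a share under 0.05. In fits of those 6 libraries the real splits gave 1458 genes in B12, 6854 in Cl.4, 5913 in B24, 4472 in Cl.3, 1701 in A7, 4556 in A10, 3302 in B14 and 2423 in B6, and the highest other was 0 in each.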

How the results depend on the processing

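The GC and length correction and the fit without libraries that stood apart were chosen after the results were seen. Of counts and summary values under an alternative, 226 stayed within 1.5 times the main count or on the same side of the threshold and 91 did not. Of single genes and lists, 1814 kept their side of the threshold, 117 passed it only under an alternative, 63 passed it only in the main setting and 0 reversed, and the cause was not tested. For high against low clones edgeR called 0 genes in the main setting. DESeq2 called 22 higher and 25 lower, limma-voom with the clone as a random effect 82 and 148, the same with a replicate block 66 and 132, and every library as its own replicate 1050 and 924. For high vs intermediate clones, genes called by these were 29, 39, 27 and 1040. For intermediate vs low clones, genes called by them were 5, 0, 0 and 400. For the trend DESeq2 called 12 rising and 13 falling, limma-voom 12 and 44, and with the replicate block 8 and 37. In leave-one-out of clones 0 to 1 genes were called higher and 0 to 1 lower between high and low clones, with 480 (without B24) to 2577 (without B12) at an unadjusted p under 0.05. These few genes, chosen after their values were seen, included ISYNA1 without B12, RNF212 without Cl.4, ELFN1-AS1 without Cl.3 or B6 and in the high and low clones alone (0 higher, 1 lower), and ARMCX1 without B14. Between high and intermediate clones 0 to 3 were called (ELFN1-AS1 without Cl.3, OSTCP1, FSTL5 and LARGE without B6) and between intermediate and low clones 0 to 4 (RNF212 without Cl.4, OSTCP1, FSTL5, LARGE and NBEAP1 without B6). Camera called 2 lists between high and low clones and 3 for the trend, and 0 and 0 with an estimated correlation. Leave-one-out of clones gave 1 list without A10 and 4 without A7, B14 or Cl.4 in the first, and 1 without A10 or B14 in the second. With the log2 fold change at least 1, clone against whole population gave 105 higher and 164 lower in B12, 228 and 626 in Cl.4, 210 and 580 in B24, 155 and 795 in Cl.3, 134 and 233 in A7, 133 and 360 in A10, 66 and 267 in B14 and 59 and 217 in B6. With the GC and length correction the higher counts were 1938 in B12, 3524 in B24, 3930 in Cl.3, 1656 in A7, 2828 in A10, 2124 in B14 and 1477 in B6. Without the libraries that stood apart A7 had 1741 higher and 1612 lower, B14 1661 higher and B6 1297 higher. Leaving out 1 replicate number gave these ranges of higher and of lower counts: B12 460 to 708 and 496 to 798, Cl.4 1537 to 2343 and 2102 to 2540, B24 1327 to 2011 and 1862 to 2283, Cl.3 1227 to 2504 and 2328 to 2995, A7 364 to 1197 and 506 to 1121, A10 1023 to 1842 and 1282 to 1896, B14 346 to 955 and 592 to 1041, B6 233 to 684 and 429 to 866. With the replicate number as a replicate block in the edgeR fit B12 had 1157 and 1243 and Cl.3 2418 and 3330, and the other clones also stayed within 1.5 times the main counts. The numbers are not known to pair samples: 14 of 27 libraries correlated best with libraries of their own number. The difference in class distance had an exact permutation p of 0.800 with Spearman, 0.661 with the 1000 most variable genes and 0.889 with the whole population counted as intermediate. The calls of single genes that ended without replicate 1 included EGFR in B14, B24 and Cl.4 (adjusted p of 0.136, 0.174 and 0.0517) and AXL in B24 and B6 (0.203 and 0.284). Leaving out a replicate number leaves fewer libraries per population, which alone can end a call or lower a count. Depth limits genes near the floor of 3 counts.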

Other observations

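The only tests in this part chosen after the results were seen are the values with the GC and length correction. Lists were not tested against other genes within a clone, so their counts are to be read beside the calls over all genes in that clone. Interferon-response genes were lower in several clones than in the whole population. Of 24 tested members 12 fell and 1 rose in B24 (13 and 1 adjusted over the list alone), 11 fell and 2 rose in Cl.3 and 10 fell and 2 rose in Cl.4 (the same adjusted over the list alone). The antiviral synthetase gene OAS3 changed by −4.52 (log2, SE 0.23) in B24 and −2.77 (SE 0.18) in Cl.3, and OAS1 by −3.84 (SE 0.20) and −2.63 (SE 0.16). With the GC and length correction the median of the interferon list went from −0.40 to −0.23 in Cl.4, from −0.38 to −0.24 in Cl.3 and from −0.58 to −0.54 in B24. Basal and squamous markers differed in both directions: of 20, 10 rose and 1 fell in B24 (the same adjusted over the list alone), while 11 fell in Cl.4 and 11 in Cl.3, with 4 and 3 higher (11 and 12 fell, 5 and 3 rose adjusted over the list alone). The basal keratin gene KRT5 changed by 1.10 (SE 0.09) in B24, −3.42 (SE 0.11) in Cl.4 and −3.93 (SE 0.12) in Cl.3, and SERPINB4 by 3.02 (SE 0.24) in B24.

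Genes of the unfolded protein and amino acid stress response fell in Cl.3 (16 of 25, with 3 higher) and Cl.4 (12 of 25, with 2 higher), the same adjusted over the list alone. In the high clone B12 6 of them rose and 1 fell (8 and 1 adjusted over the list alone). XBP1, a transcription factor of that response, changed by −1.14 (SE 0.07) in Cl.3 and −0.74 (SE 0.07) in Cl.4, and EDEM1 by −1.17 (SE 0.10) and −1.20 (SE 0.10). With the GC and length correction the median of the list went from −0.40 to −0.24 in Cl.3 and from −0.23 to −0.12 (−0.115) in Cl.4. Of 13 Wnt targets 11 fell and 0 rose in Cl.3 (12 and 0 adjusted over the list alone), with DKK1, a secreted Wnt antagonist, at −0.89 (SE 0.07). Of 17 receptor tyrosine kinases other than EGFR and their ligands 9 rose and 3 fell in B24 (9 and 4 adjusted over the list alone), with FGFR1 at 2.04 (SE 0.12). Of 30 G1/S replication genes 14 rose and 3 fell in B24 (15 and 4 adjusted over the list alone), with MCM2 at 0.69 (SE 0.09) and cyclin E1 (CCNE1) at 0.56 (SE 0.07).

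Of the 4 lists with too few tested genes, HLA class II had 2 tested genes (highest HLA-DMA at 1.502 CPM), fibroblast markers 4 (highest FBLN1 at 284 CPM), endothelial markers 4 (highest ESAM at 64.2 CPM) and mitochondrially encoded messenger RNAs 0. Between high and low clones the median, the mean and the camera direction differed in sign for 5 lists: TGF-beta targets (−0.02 and 0.18, up), kinases that phosphorylate IRS proteins on serine (0.01 and −0.06, down), NRF2 targets (−0.05 and −0.01, up), oxidative phosphorylation (0.01 and −0.02, down) and haematopoietic markers (−0.07 and 0.03, down). For the trend they differed for NF-kB targets, glycolysis, TGF-beta targets, NRF2 targets, oxidative phosphorylation, aldehyde dehydrogenases and fatty acid synthesis.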
